A study of Mus musculus with 4 samples.

How the data were processed

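RNA was measured in 4 libraries of primary cells from mouse calvaria (skull bone), 2 infected with an adenovirus carrying Cre and 2 with one carrying YFP. The cells came from C57BL/6 mice at postnatal day 10 with floxed alleles of the miR-17 cluster (miR-17, miR-18a, miR-19a, miR-20a, miR-19b and miR-92a) and no functional miR-106b cluster (miR-106b, miR-93 and miR-25), so that Cre recombinase, which cuts out DNA between loxP sites, removes the miR-17 cluster on a background that lacks the miR-106b cluster in both groups. Per the labels, more than 80% of cells were infected, RNA was taken 3 days after infection, polyadenylated RNA was enriched from 1 ug of total RNA, and single-end libraries of a planned 30 M reads were sequenced on the BGISEQ-500.

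The deposited values are FPKM (fragment numbers scaled to transcript length and to the mapped reads of the library), 1 column per library, which the authors gave to 2 decimals for 19171 genes with Entrez and RefSeq transcript identifiers. Bowtie 02.2.5 and the genome build mm8 are named per the submitters' processing notes. The program that made the FPKM values, its annotation release and its use of strand are not given in the sources used here. Each library was assigned through the number in its column name, which matches the description of 1 sample. Read counts were not used here, so absolute depth is unknown and no counting interval is given. In short RNA genes, values were taken as whole multiples of what 1 read is worth, and the most frequent ratio between libraries put the worth of 1 read at 1.025, 1.015 and 1.012 times that of YFP replicate 1 in YFP replicate 2, Cre replicate 1 and Cre replicate 2. Those ratios rest on 10, 15 and 9 genes, respectively.

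The design fixed before the data were examined foresaw a count test for a table of counts and a linear model for FPKM, and the FPKM branch applied. Genes with an FPKM of at least 1 in at least 2 libraries were tested (12046 genes). Values were transformed as log2(FPKM + 1), and the groups were compared with limma 3.58.1 (trend and robust empirical Bayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and ratios of mean FPKM are named as such. Nothing in the labels says that the 2 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Virus insert and deletion differ together between the groups.

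Before the data were examined, 29 gene lists were fixed from general knowledge, for pathways linked to these miRNAs, bone cell differentiation, cell cycle, stress, and markers of other cell types. The 27 with at least 5 tested members were compared with all other tested genes by camera on the moderated statistics with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. The estimated variant rests on few residual degrees of freedom, so a call lost in it need not be due to correlation between genes. The skeletal muscle and erythroid lists had too few tested members.

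For target sites, each of the 16384 possible 7-mers was scored for presence in the longest annotated 3′ UTR of 11522 tested genes (GENCODE M21). The log2 fold change was regressed on presence with log2 UTR length, UTR GC fraction and mean log2 expression as covariates. The sites of the 4 seed families were ranked by coefficient over standard error among the 16115 7-mers found in at least 50 genes, and the two-sided share of 7-mers as extreme was adjusted over the 4 families. GENCODE M21 is on another build than mm8, so no coordinates are given.

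Both procedures were tested on simulated data. With 200 of 12046 genes changed, limma recovered 56.7% at 1.25-fold, 82.1% at 1.5-fold and 97% at 2-fold. It made 14 false calls beside 157 true ones, a false share above the threshold of 0.05, and 0 calls when nothing was changed. The simulated errors were independent between genes and drawn from the variance that limma had fitted. Far fewer genes were changed than the 3961 called in the data, so the error rate of the real comparison was not tested. A 7-mer given an effect of 0.05 on shuffled fold changes ranked 1 of all 7-mers. That effect was larger than the coefficients of the seed sites (at most 0.0212 for 7-mers), and shuffling removed the trend of fold changes with UTR GC. Detection of effects as small as those of the seed sites was therefore not tested.

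Named genes follow a rule set before the data were examined: 6 genes fixed by name, of which Mir17hg, Mcm7, Tgfbr2, Bcl2l11 and Cdkn1a are described; the 10 largest rises and 10 largest falls past the threshold with a mean FPKM of at least 1 in the higher group and no overlap between groups, leaving out unnamed gene models; up to 4 members of each described list with the smallest unadjusted p; and genes with a site of any seed family in the outer 1 percent of 7-mers, which none reached. Genes named outside it are marked as such. Alternatives were 2 other scalings, a pseudocount of 0.1, no filter, a mean FPKM of at least 5, the replicate number as a block, each library left out, a minimum of 1.5-fold, and for sites the 8mer, another UTR choice and no covariates. Removal of the GC and length trend was added after seeing the data. A count-based alternative was not run because the values are FPKM. Genes with near-identical copies, such as histones, Hspa1b and interferon-induced families, are uncertain, since the authors' handling of shared reads is not given in the sources used here.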

Results

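The comparison asks how loss of the miR-17 cluster, on a background without the miR-106b cluster, changed the transcriptome of calvarial cells, a culture of bone-forming and other cells released from skull bone by collagenase. There were 2 libraries with Cre adenovirus and 2 with YFP adenovirus. FPKM values summed to 458756 and 462419 in the YFP libraries and to 461677 and 471021 in the Cre libraries, and the 10 most abundant genes held 6.45% to 6.83% of each sum. Pearson's r across genes, which are not independent replicates, was 0.9967 between the YFP libraries, 0.9973 between the Cre libraries and 0.9877 to 0.9893 across groups. The leading principal component held 77.0% of the variance and separated the groups. The groups differed in the protein the virus carried as well as in the deletion, and Cre virus on cells without floxed alleles is not analysed here.

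With Cre, genes of cell division and of sterol synthesis were lower, with 36 of 36 genes of G2 and mitosis and 16 of 20 of sterol synthesis falling (camera adjusted p = 1.71e-20 and 1.53e-08, and adjusted p = 0.223 and 0.41 with an estimated correlation). Interferon-stimulated genes and inflammation genes were higher, with 23 of 25 and 15 of 21 rising (camera adjusted p = 2.15e-14 and 1.48e-10, and adjusted p = 0.442 and 0.41 with an estimated correlation). As ratios of mean FPKM, Cdkn1a rose 1.44-fold, Ccl2 3.58-fold and the keratin gene Krt18 9.58-fold, while the elastin gene Eln and the tendon gene Tnmd fell to 0.37 and 0.41 of their YFP means.

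Mir17hg (Entrez 75957), the host transcript of the miR-17 cluster, was 3.60 ± 0.44 FPKM (SD, n = 2) with YFP and 7.92 ± 0.81 with Cre, and it rose by 0.96 on the log2 scale (SE 0.09, limma adjusted p = 3.62e-05). The transcript model behind this value does not check the deletion. Of its 2339 nt, 95% lie downstream of the last miRNA of the cluster, 4 of the 6 miRNAs lie wholly upstream of it, and 0 miRNA genes of either cluster are listed in the table. Mcm7 (Entrez 17220), a DNA replication helicase gene that hosts the miR-106b cluster, was 35.8 ± 1.4 FPKM with YFP and 31.6 ± 1.7 with Cre and fell by 0.18 (limma adjusted p = 0.0265). That call was lost without YFP replicate 1 (adjusted p = 0.103), without Cre replicate 1 (adjusted p = 0.238), without Cre replicate 2 (adjusted p = 0.056) and with no filter on low values (adjusted p = 0.0779).

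Tgfbr2, Bcl2l11 and Cdkn1a, also named in advance, are reported targets of these miRNAs. Cdkn1a (Entrez 12575), an inhibitor of cyclin-dependent kinases, rose from 403.1 ± 31.3 to 581.3 ± 22.1 FPKM (log2 change 0.53, SE 0.06, limma adjusted p = 9.78e-05). Bcl2l11 (Entrez 12125), which encodes the pro-apoptotic protein BIM, rose from 2.27 ± 0.23 to 2.84 ± 0.13 FPKM (log2 change 0.23, limma adjusted p = 0.0454), a call lost without YFP replicate 1 (adjusted p = 0.225), without Cre replicate 1 (adjusted p = 0.222), without Cre replicate 2 (adjusted p = 0.124), with a replicate block (adjusted p = 0.0732) and with no filter (adjusted p = 0.0915). Tgfbr2 (Entrez 21813), a TGF-β receptor gene, was 65.6 ± 0.1 and 65.4 ± 2.1 FPKM (limma adjusted p = 0.949).

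By the rule for named genes, the largest rise was that of Krt18 (Entrez 16668), an epithelial keratin gene, from 0.94 ± 0.04 to 8.96 ± 0.59 FPKM (log2 change 2.36, SE 0.07, limma adjusted p = 2.20e-08). Ccl2 (Entrez 20296), a monocyte-attracting chemokine, rose from 39.6 ± 1.7 to 141.5 ± 3.5 FPKM (log2 change 1.81). The next largest rises were those of Sncg (log2 change 1.73), Zbp1 (1.65), Isg15 (1.63), Hist1h4h (1.59, a histone gene with near-identical copies), Mmp10 (1.57), Sbsn (1.56), Il11 (1.55) and Cck (1.51). Zbp1 and Isg15 are interferon-induced, Mmp10 is a matrix metalloproteinase, Il11 is a cytokine and Cck a peptide hormone. Isg15 was not past the threshold without YFP replicate 1 (adjusted p = 0.0622) or without YFP replicate 2 (adjusted p = 0.0619), with log2 changes of 1.64 and 1.61.

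Among the falls, Eln (Entrez 13717), which encodes elastin, went from 22.45 ± 0.55 to 8.39 ± 0.22 FPKM (log2 change -1.32, SE 0.05, limma adjusted p = 1.19e-07). Tnmd (Entrez 64103), a tendon marker, fell by 1.26 on the log2 scale, from 101.8 ± 3.8 to 41.8 ± 1.0 FPKM. Fbn2, which encodes the microfibril protein fibrillin-2, fell by 1.25. Otor fell by 1.29, Zcchc5 by 1.18 and Trib3, a stress-induced pseudokinase gene, by 1.04. The other 4 of the 10 largest falls were short RNA genes, a class that polyA libraries cover poorly. Snord57 was listed at 3.89 and 2.99 FPKM with YFP and Mir3100 at 2.71 and 1.85, and both were listed at 0 in each Cre library. Snora17 fell by 1.26, and Snora15 by 1.10, a call lost with a pseudocount of 0.1, where the log2 change was -2.92 (limma adjusted p = 0.142).

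Across all tested genes, 3961 of 12046 passed the threshold in limma, 1998 higher and 1963 lower with Cre. Of these, 311 rises and 82 falls reached 1.5-fold. With a pseudocount of 0.1 there were 508 and 170. Among the 8458 genes with a mean FPKM of at least 5 there were 153 and 46. The near-even balance of all calls depended on the setting. It was 2179 higher and 1742 lower with median-of-ratios scaling, 2155 and 1820 with GC and length removed, and 1960 and 1439 with no filter. It tipped the other way, to 1453 and 1579, at a mean FPKM of at least 5. Of the 3961 calls, 3740, 3301, 2882 and 2854 were made again in these settings, which tested 12046, 11663, 19171 and 8458 genes. The count itself was 3921, 3975, 3399 and 3032. The count dropped to 1872 without Cre replicate 2 and to 2384 without Cre replicate 1, of which 1829 and 2308 were also called with all libraries.

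**Figure D1:**
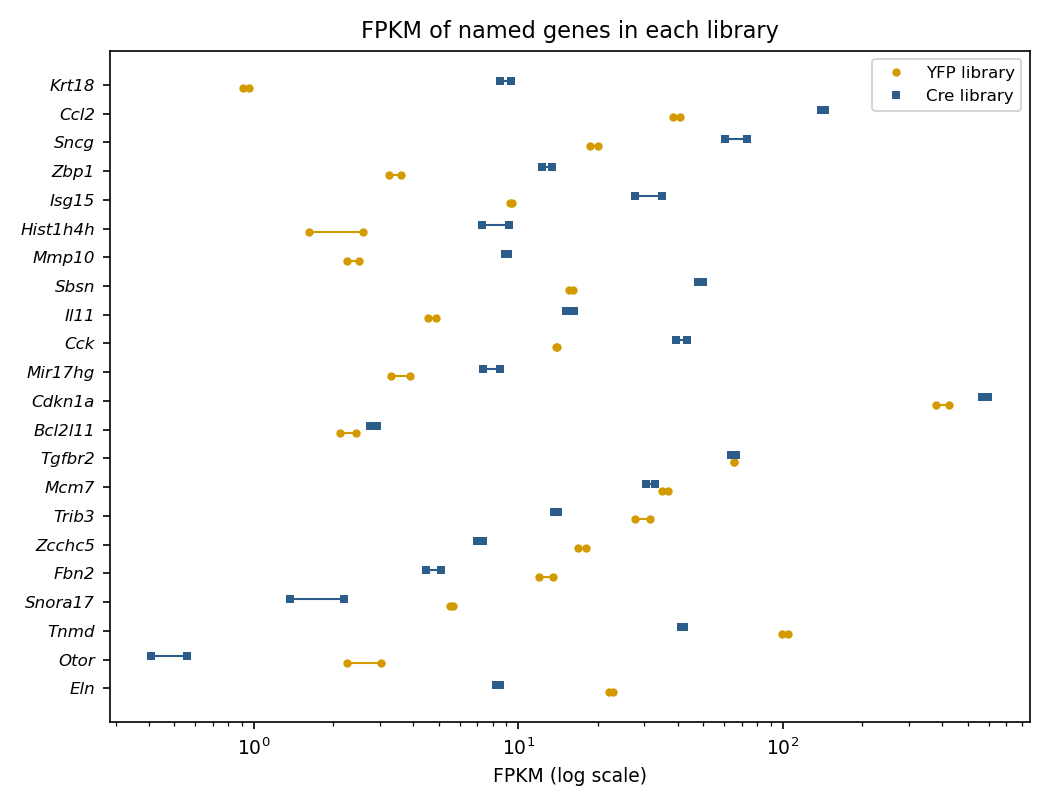
FPKM on a log axis of 5 genes named in advance and of the largest rises and falls; each circle is a YFP library, each square a Cre library, and lines join the 2 libraries of a group. Genes listed at 0 in any library are left out, and Krt18 shows the widest gap, from 0.91 and 0.96 to 8.54 and 9.38.

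Genes of cell division were lower with Cre. All 36 tested genes of G2 and mitosis fell, with a median log2 change of -0.42 (36 also adjusted over the list alone; camera adjusted p = 1.71e-20, and adjusted p = 0.223 with an estimated correlation). Ccna2, a cyclin of S phase and G2, fell from 45.9 ± 0.3 to 30.2 ± 0.4 FPKM, and the mitotic cyclin genes Ccnb1 and Ccnb2 and the kinetochore gene Nuf2 fell by 0.55, 0.57 and 0.56 on the log2 scale. Of 33 genes of DNA replication and S phase, 23 fell and 0 rose (25 fell adjusted over the list alone; camera adjusted p = 1.26e-07, and adjusted p = 0.41 with an estimated correlation). They included Rrm1, a ribonucleotide reductase gene, with a log2 change of -0.32, Mcm6 with -0.31, Ccne2 with -0.41 and Rfc4 with -0.49.

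Genes of sterol synthesis were lower as well. Of 20, 16 fell and 0 rose (17 fell adjusted over the list alone; camera adjusted p = 1.53e-08, and adjusted p = 0.41 with an estimated correlation). Hmgcs1, an enzyme of the mevalonate pathway, fell from 77.2 ± 2.0 to 52.1 ± 1.9 FPKM. Fdps fell by 0.49, Idi1 by 0.45 and Insig1 by 0.45 on the log2 scale.

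Interferon-stimulated genes were higher with Cre. Of 25 tested, 23 rose and 0 fell, with a median log2 change of 0.93 (24 rose adjusted over the list alone; camera adjusted p = 2.15e-14, and adjusted p = 0.442 with an estimated correlation). Zbp1, a nucleic acid sensor, rose from 3.42 ± 0.26 to 12.9 ± 0.8 FPKM, Xaf1 rose by 1.17 on the log2 scale, Ifih1, a sensor of double-stranded RNA, by 0.70, and Irf9 by 0.59. Of 21 inflammation genes, 15 rose and 1 fell (17 and 2 adjusted over the list alone; camera adjusted p = 1.48e-10, and adjusted p = 0.41 with an estimated correlation). Beside Ccl2, Il11 and Mmp10, the stromelysin gene Mmp3 rose by 0.91 on the log2 scale. Of 20 immediate early and heat shock genes, 13 rose and 0 fell (14 rose adjusted over the list alone; camera adjusted p = 4.83e-06, and adjusted p = 0.41 with an estimated correlation), among them Ier3 (log2 change 0.85), Dusp1 (0.60), Nr4a1 (0.48) and Hspa1b (0.39).

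Markers of macrophages and other leukocytes moved in the same direction as the interferon and inflammation genes. Of 13, 6 rose and 0 fell (8 rose adjusted over the list alone; camera adjusted p = 0.0126, and adjusted p = 0.492 with an estimated correlation), and the call was lost without Cre replicate 2 (adjusted p = 0.0644) and with fry (adjusted p = 0.0995). Lyz2, the lysozyme gene of myeloid cells, rose from 77.4 ± 3.4 to 101.9 ± 4.0 FPKM, and Tyrobp, Laptm5 and Csf1r rose by 0.39, 0.35 and 0.33 on the log2 scale, with the call of Csf1r lost without Cre replicate 2 (adjusted p = 0.0931). The osteoclast list passed with 2 of 6 members higher (3 adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.41 with an estimated correlation), Acp5 by 0.49 and Mmp9 by 0.51, and the list call was lost without YFP replicate 1 (adjusted p = 0.0523), that of Acp5 without Cre replicate 2 (adjusted p = 0.0703). Of 9 neuronal and glial markers, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 5.09e-04, and adjusted p = 0.41 with an estimated correlation). Nes, an intermediate filament gene of progenitor cells, rose by 0.68, Ngfr by 0.45, S100b by 0.33 and Tubb3 by 0.27, the last a call lost without Cre replicate 2 (adjusted p = 0.0555).

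Of 25 p53 target genes, 12 rose and 4 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.0058, and adjusted p = 0.41 with an estimated correlation). Mdm2, the p53 ubiquitin ligase gene, rose from 65.8 ± 2.8 to 94.7 ± 0.7 FPKM, Perp by 0.56 on the log2 scale and Ei24 by 0.35. Of 27 components of TGF-β and activin signalling, 12 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.00226, and adjusted p = 0.487 with an estimated correlation). The members with the smallest p were Ltbp2 (log2 change 0.63) and Ltbp3 (0.34), which encode latent TGF-β binding proteins, and the ligand genes Tgfb2 (0.55) and Inhbb (0.38).

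**Figure D2:**
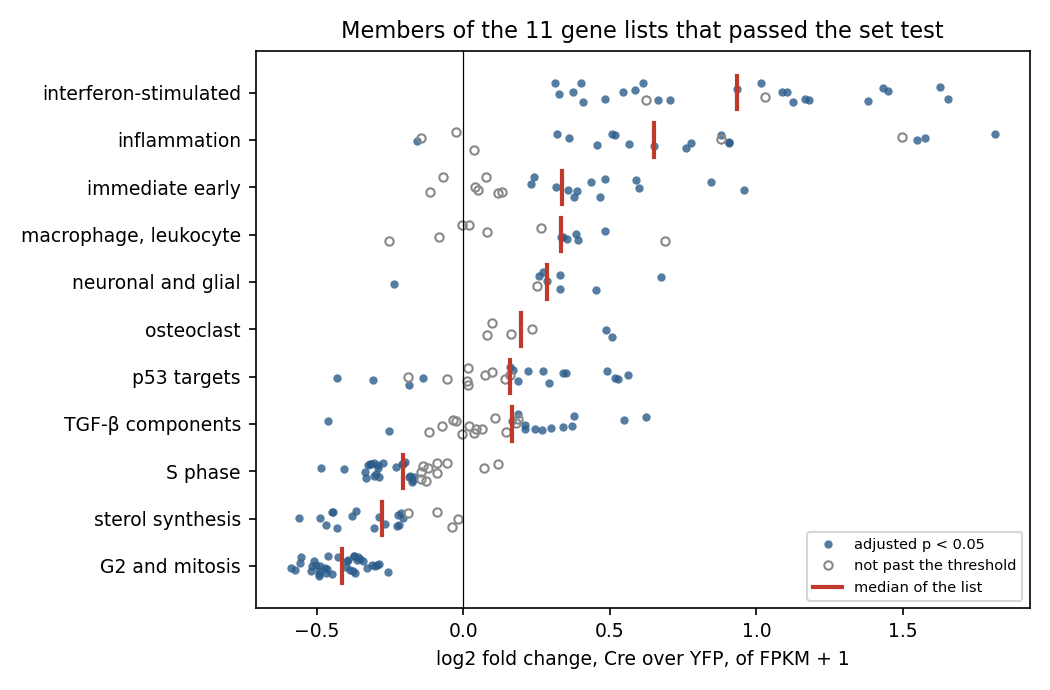
Log2 fold change, Cre over YFP, of FPKM + 1 for each tested member of the 11 lists that passed camera with a preset correlation; filled points passed limma's adjusted threshold, open points did not, and red bars are list medians. All 36 genes of G2 and mitosis lie below 0, and the interferon-stimulated genes have a median of 0.93.

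The other 16 tested lists did not pass. Of 45 reported targets of the miR-17 and miR-106b clusters, 12 rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.237). Ctgf, a matricellular gene, rose by 0.52 on the log2 scale and Itga5 by 0.42, while Osr1 fell by 0.39. Of 19 osteoblast genes, 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.647), with Pdpn higher by 0.65 and Omd lower by 0.63. Of 35 matrix genes, 9 rose and 18 fell (9 and 18 adjusted over the list alone; camera adjusted p = 0.0976), with Col18a1 higher by 0.42 and Col11a1 lower by 0.60. That list passed without YFP replicate 2 (adjusted p = 0.0406), without Cre replicate 1 (adjusted p = 0.0264), with no filter (adjusted p = 0.0242) and with the GC and length trend removed (adjusted p = 0.0465). Of 24 TGF-β response genes, 11 rose and 7 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.151). Of 25 PI3K and AKT pathway genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.374).

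Rises and falls in the remaining lists were as follows, adjusted over the list alone in brackets. In the BMP pathway, 7 rose and 5 fell of 23 (7 and 6; camera adjusted p = 0.787). In the Wnt pathway, 10 rose and 10 fell of 23 (10 and 10; adjusted p = 0.764). Among stress response genes of the endoplasmic reticulum, 4 rose and 6 fell of 18 (4 and 6; adjusted p = 0.0976), a list that passed without YFP replicate 2 (adjusted p = 0.0406) and with no filter (adjusted p = 0.0267). In glycolysis and hypoxia, 4 rose and 7 fell of 25 (5 and 7; adjusted p = 0.908), and among apoptosis genes 4 rose and 4 fell of 20 (4 and 4; adjusted p = 0.908). Among chondrocyte markers, 1 rose and 4 fell of 10 (1 and 5; adjusted p = 0.121), and that list passed with no filter (adjusted p = 0.0468). Among fibroblast markers, 5 rose and 6 fell of 15 (5 and 6; adjusted p = 0.908). Adipocyte markers gave 3 and 2 of 8 (3 and 2; adjusted p = 0.844), endothelial markers 2 and 1 of 6 (3 and 1; adjusted p = 0.181), and smooth muscle and pericyte markers 2 and 2 of 11 (2 and 2; adjusted p = 0.884). A list of miRNA host genes, genes of the miRNA machinery and Myc gave 1 and 1 of 7 (1 and 1; adjusted p = 0.648). The median was negative and the mean positive in the BMP (-0.03 and 0.07), fibroblast (-0.07 and 0.05) and apoptosis (-0.01 and 0.01) lists, where the test pointed up. The same held in the list of miRNA hosts, machinery and Myc (-0.09 and 0.05), where the test pointed down. In glycolysis the median was 0.03, the mean -0.01 and the test pointed up.

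Genes with 3′ UTR sites for the deleted miRNAs were compared with genes without, as a test of release from repression in these libraries. Presence of the miR-92 family site GTGCAAT (876 genes) went with a log2 fold change higher by 0.021 (SE 0.0087), and 1.3% of the 16115 7-mers ranked as high. For the miR-17 family site GCACTTT (1703 genes) the coefficient was 0.015 (SE 0.0067) and 2.13% ranked as high, for the miR-19 site TTTGCAC (1579 genes) 0.012 (SE 0.0068) and 4.63%, and for the miR-18 site GCACCTT (1055 genes) 0.0028 (SE 0.008) and 34.99%. The two-sided shares were 0.026, 0.043, 0.093 and 0.70, and adjusted over the 4 families they were 0.085, 0.085, 0.123 and 0.70, so that no family passed with this site definition. The miR-92 site passed without Cre replicate 2 (adjusted share 0.0308), and the miR-17 and miR-92 sites passed among genes with a mean FPKM of at least 5 (0.0336 each) and with the GC and length trend removed (0.0382 each).

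With the stricter 8mer, in which an A follows the site, 3 families passed: miR-17 (519 genes, coefficient 0.044, SE 0.011, adjusted share 0.0012), miR-19 (713 genes, 0.023, SE 0.0095, adjusted share 0.0214) and miR-92 (335 genes, 0.031, SE 0.0135, adjusted share 0.0214). The miR-18 8mer (198 genes) had a coefficient of -0.0015 (adjusted share 0.99). The 8mers were fitted only with all libraries and with the covariates. Their calls were therefore not put through the alternatives run for the 7-mers. The 7-mer coefficients depended on the covariates, and without them they were -0.016, -0.0097, -0.020 and -0.011 for miR-17, miR-18, miR-19 and miR-92, where 52.16%, 35.99%, 57.85% and 36.03% of 7-mers ranked as high and each adjusted share was 0.957. Fold changes rose with UTR GC content across genes, from a mean of -0.072 in the fifth of genes with the lowest GC to 0.09 in the fifth with the highest.

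**Figure D3:**
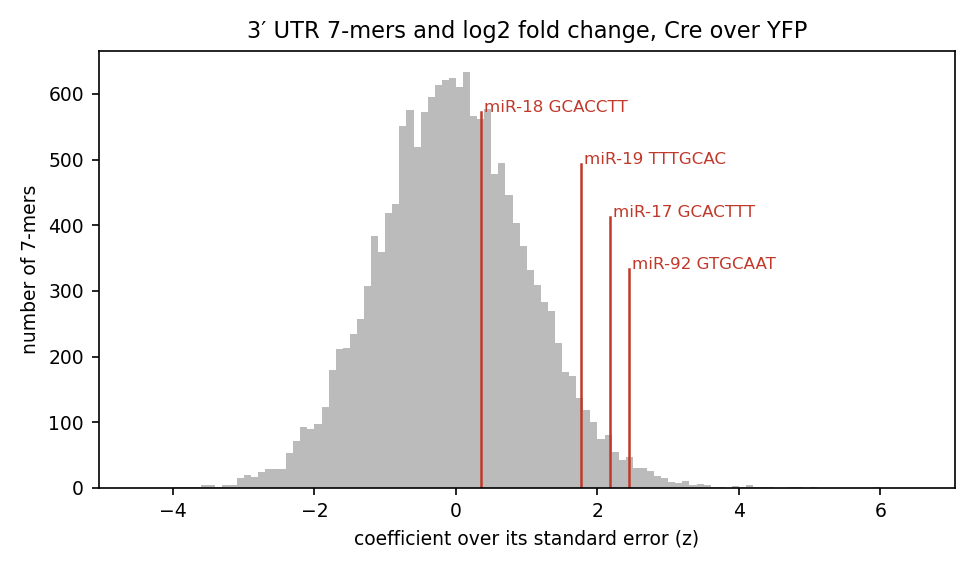
Number of 7-mers by the coefficient over its standard error from the regression of log2 fold change on presence in the 3′ UTR; grey bars hold all 16115 ranked 7-mers and red lines mark the sites of the 4 seed families. The sites of miR-92, miR-17 and miR-19 lie in the upper tail, where 1.3%, 2.13% and 4.63% of 7-mers rank as high.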

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

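Among the 7125 genes below the FPKM filter, which were tested only in the alternative with no filter, 268 were listed above 0 in both Cre libraries and at 0 in both YFP libraries, up to 2.49 FPKM, while 90 showed the opposite pattern. They drew attention because more genes were detected with Cre (17952 and 17891 above 0) than with YFP (17452 and 17445).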

How the results depend on the processing

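Removal of the GC and length trend, and the pseudocount of 0.1 for sites, were chosen after seeing the data. The count of 3961 genes stayed within 1.5 times under both other scalings, the other pseudocount, both filters and the GC and length correction (3032 to 3975). It ranged from 1872 (without Cre replicate 2) to 3560 (without YFP replicate 2) when 1 library was left out, where the lone library is assumed to vary like the other group, and 393 genes also reached 1.5-fold (678 with a pseudocount of 0.1, 199 with a mean FPKM of at least 5). Same-numbered libraries did not deviate together (correlation -0.031), and the replicate block gave 3533 genes and lost none of the list calls. The other 2 splits into pairs each gave 0 genes in limma. Their groups mix YFP with Cre, so that difference adds spread and the calls go untested. The splits are too few for a share under 0.05. The planned count test was not run, since the values are FPKM, and limma on log2(FPKM + 1) is the test used throughout.

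With an estimated correlation, none of the 11 called lists passed: adjusted p was 0.223 for G2 and mitosis, 0.442 for interferon, 0.487 for TGF-β components, 0.492 for macrophages, and 0.41 for S phase, p53, inflammation, sterols, osteoclast, neuronal and immediate early genes. This variant estimates the correlation, and judges its statistic, from few residual degrees of freedom, so it has little power with 4 libraries. The estimated correlation was -0.01 for G2 and mitosis, -0.03 for p53 and -0.15 for osteoclast, all below the preset 0.01. It was higher for the other called lists, up to 0.67 for interferon. For G2 and mitosis, p53 and osteoclast, correlation between genes therefore does not account for the lost call. With fry, which does not compare a list with other genes, macrophages were lost (0.0995) and TGF-β response (0.0245), chondrocyte (0.00604), fibroblast (0.0362), endothelial (0.0455) and endoplasmic reticulum stress (0.0326) lists passed. With no filter, matrix (0.0242), chondrocyte (0.0468) and endoplasmic reticulum stress (0.0267) lists passed, and the matrix list passed with GC and length removed (0.0465). Leaving out 1 library gave 0.0264 to 0.217 for matrix, 0.00172 to 0.0644 for macrophages, 0.0258 to 0.0523 for osteoclast and 0.0406 to 0.166 for endoplasmic reticulum stress. The cause was not tested for these lists. No list reversed.

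Mcm7 kept its direction (log2 change -0.18 with no filter, -0.23 to -0.12 with 1 library left out) and lost its call with no filter and in 3 of the 4 fits without a library, but not without YFP replicate 2 (adjusted p = 0.0166). Of 1410 other values of 132 named genes, hosts included, 1370 kept their side of the threshold, 36 lost it and 4 gained it. A reversal was counted only where the gene was called in the main fit or the alternative, and there were 0. Changes of sign in genes called in neither fit were not counted.

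Site results depended on the definition. Adjusted shares passed for 8mers (miR-17 0.0012, miR-19 0.0214, miR-92 0.0214), for a mean FPKM of at least 5 (miR-17 and miR-92 0.0336) and with GC and length removed (miR-17 and miR-92 0.0382). Leaving out 1 library gave 0.0308 to 0.1522 for miR-92, passing without Cre replicate 2. The cause was not tested. Fewer reads limit low genes most, and without counts that limit has no value here.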

Other observations

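The 5 gene lists of the next paragraph, the leukocyte and virus tests, the summed score of the 4 families and the interest in miR-29 were chosen after results were seen. For the composition test, the test in genes without TGGTGCT and the test without matrix genes, the outcome that would count for or against was set before they were run, but the distance of GGTGCTA from its bound in standard errors was computed after its share was seen.

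Keratin and epithelial genes were higher with Cre, 14 of 15 tested from a list of 37 (camera adjusted p = 4.82e-10, and adjusted p = 0.0812 with an estimated correlation). Krt18 and Dsp were below an FPKM of 1 in both YFP libraries and passed the filter only through the Cre libraries. The share of tested genes that rose may thus overstate that of the class. Krt7 went from 1.25 ± 0.08 to 5.22 ± 0.68 FPKM and Dsp, a desmosome gene, from 0.34 ± 0.05 to 1.97 ± 0.05. All 9 tested mesothelial markers, from a list of 15, were higher (camera adjusted p = 5.36e-10, and adjusted p = 0.0812 with an estimated correlation). Among them were Aldh1a2 and Slpi with log2 changes of 1.29 and 1.39, and keratins are shared between the lists. Of 17 tendon and elastic fibre genes, 11 were lower and 1 higher (camera adjusted p = 2.10e-07, and adjusted p = 0.14 with an estimated correlation), with Mgp, a calcification inhibitor, falling from 574.5 ± 6.1 to 288.9 ± 5.2 FPKM and Igsf10 by 0.94 on the log2 scale. Of 23 replication-dependent histone genes, 18 were higher and 0 lower (camera adjusted p = 3.89e-09, and adjusted p = 0.122 with an estimated correlation), although S phase genes fell. Histone genes share reads between copies and most lack a polyA tail, so these values are uncertain. Of 64 snoRNA genes, 2 were higher and 8 lower (camera adjusted p = 0.325, and adjusted p = 0.528 with an estimated correlation). Because the lists were drawn up from genes seen to change, their p-values are not independent evidence.

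Interferon-stimulated genes were higher with Cre by a median log2 ratio of mean FPKM of 1.25 (95% bootstrap interval over genes 0.67 to 1.48). A larger share of leukocytes would raise leukocyte markers at least as much, but the median of the 13 tested markers was 0.44 (0.03 to 0.55), with 0 genes shared with another fixed list. Lyz2, their most abundant marker, rose from 77.4 to 101.9 FPKM and Cd68 was 7.58 and 12.7 FPKM (limma adjusted p = 0.0552), but C1qb was 2.42 and 2.23 and C1qc 1.56 and 1.55 (Cd68, C1qb and C1qc were picked after their values were seen). The intervals treat the genes of a list as independent, although the estimated correlation was 0.67 in the interferon list, and leave out the spread between libraries. They may thus be too narrow. The 13 markers are mostly those of macrophages. Their upper bound of 0.55 lies only just below the interferon bound of 0.67. With intervals that may be too narrow, this does not decide whether more macrophages were the whole source. Other leukocytes, a smaller contribution and activation of cells already present also stay open. A difference in virus dose or the Cre protein itself could also account for the rise and cannot be told apart from loss of the miRNAs, because 0 transcripts of the virus or its inserts are listed and every deleted culture also received Cre.

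The 4 seed sites together had a summed z of 6.73, a value reached by 11 of 10000 random quartets of 7-mers with a similar number of genes and by 0 of 10000 with the same base counts and CpG number (mean -0.65, SD 1.94). For 8mers the sum was 8.67, again with 0 of 10000. Base composition of the sites as scored here therefore does not account for the sum. Without covariates the sites of miR-17, miR-18, miR-19 and miR-92 ranked near the middle, with 52.16%, 35.99%, 57.85% and 36.03% of 7-mers as high, and genes with sites of no family, 1 family and 2 or more families had median log2 changes of -0.009, -0.017 and -0.023, with 17.3%, 16.3% and 14.4% past the threshold upwards and 16.8%, 16.2% and 16.1% downwards. A small release of targets from the deleted miRNAs is a candidate explanation that no test here decides.

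The lowest of all ranked 7-mers was TGGTGCT, the site of miR-29, a miRNA known to repress matrix genes such as Eln (1829 genes, coefficient -0.026, SE 0.0064, z -4.00). Without 252 matrix genes, 1776 genes with the site remained, the coefficient was -0.025 and the site still ranked within the lowest 0.02% of 7-mers. The low rank thus does not rest on those matrix genes alone. Since TGGTGCT was picked as the lowest 7-mer, this does not show that there is an effect to explain. The other miR-29 site type, GGTGCTA, in genes without TGGTGCT lay in the lowest 1.28% (432 genes, coefficient -0.029). Base composition or a chance extreme cannot be told apart from an effect of miR-29: 31 of 100 shuffles of the fold changes held a 7-mer as low as TGGTGCT, GGTGCTA passed its bound of the lowest 5% by 0.62 of its standard error, less than its spread, and the 8mer gave a coefficient of -0.017 with 8.99% of 8mers as low. miR-29 itself was not measured by these polyA libraries.

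At the other end, the 3 highest 7-mers were CACCCCC, CCCCCAC and ACCCCCA (z 5.97, 5.02 and 4.87), farther from 0 than TGGTGCT and than the site of any deleted family, and 0 of 100 shuffles held a 7-mer with a z of 5.97. These 7-mers overlap in sequence and are rich in C, so they are not separate results. The shuffles kept only the linear trend with UTR GC and the other covariates. They therefore do not test base composition as a source of the high z.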
